A study of Arabidopsis thaliana with 30 samples.

How the data were processed

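RNA from 30 Arabidopsis samples was hybridized to Affymetrix arrays, 1 array per sample, after biotin labelling by standard Affymetrix procedures per the labels. The samples cross 2 genotypes, WT Col-0 and the pif1 pif3 pif4 pif5 quadruple mutant pifq, with 4 conditions. Per the labels, seeds were plated under white light for 1.5 h and stratified for 5 d at 4 °C. Seedlings were extracted at an age of 2 d at 21 °C, and 400 mg of tissue was extracted. Groups in darkness, in continuous red light (6.7 µmol/m2/s, 45 h) and in darkness followed by 1 h of red light (7.5 µmol/m2/s) are whole seedlings. The labels also describe a red pulse of 5 min at 46 µmol/m2/s and, after 3 h of darkness, a far-red pulse of 5 min at 58 µmol/m2/s. Dark groups held 6 arrays each and the other 6 groups 3 arrays each.

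The deposited values are log2 RMA signals: the authors processed the arrays with RMA, which corrects background, equalizes the array distributions and summarizes each probe set. Its version, the chip definition and which arrays were normalized together are not given in the sources used here. That the unit is log2 was read from the values, which ran from 2.43 to 14.5 with no zero or negative value. Array medians ran from 4.91 to 4.94 in seed and from 5.06 to 5.22 in seedlings. The values were used as deposited, with no further scaling and no filter on low values. The number of arrays per group limits the precision.

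Of 22810 probe sets, 64 control probe sets were left out and 22746 tested. A probe set table given with the data named 1 gene for 13513 probe sets, several for 503 and none for 8730, which were tested but never named. 13436 of the 13513 matched the reference gene table (assembly TAIR10.1) by gene ID, and that table was used for names only. 1580 probe sets, for 1557 genes, had a symbol other than the locus tag. A gene with several probe sets was represented by the one with the highest mean over all arrays. Many familiar genes fell among the unnamed probe sets, and the 4 targeted PIF genes, the brassinosteroid list, the seed storage list and the DNA replication list were not analysed here.

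Groups, comparisons, tests, thresholds, the naming rule and the main set of alternatives were fixed before the data were examined. All 30 arrays in 8 groups were fitted in one model with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without an intensity trend). The 14 comparisons are 4 genotype effects (pifq minus WT in each condition), 6 responses within a genotype (continuous red, 1 h red and seed to dark seedling), dark pifq against WT in continuous red light, and 3 interactions, each the pifq change minus the WT change. P-values were adjusted by Benjamini-Hochberg over the 22746 probe sets of a comparison, and a probe set was called at an adjusted p under 0.05 and a difference of at least 1 on the log2 scale. Errors given beside log2 differences are limma's SE, and those beside levels are SD over the arrays of the group.

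The genes named are, per direction, the 8 called genes with the largest difference in the dark genotype effect, the WT continuous red response and the WT 1 h red response, and the 3 in each other comparison. They were taken from probe sets with 1 gene and a symbol, and outside the interactions their arrays do not overlap between the groups. Up to 4 members of each gene list with the largest differences could be named besides. Where fewer genes met the rule, fewer are named. That a symbol must differ from the locus tag was decided after the gene table and before any gene's value was seen.

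Gene lists were tested with limma's camera at its preset correlation of 0.01 and again with an estimated correlation, with 280 list tests adjusted together. 20 lists with 321 members were written before the data were examined; 46 of their 316 loci were named in the probe set table and 8 lists had the 3 measured genes the test needs. 12 further lists were built from the symbols of the gene table, after that table and before any gene's value was seen. Of the 280 tests, 126 passed at the preset correlation and 31 with an estimated one.

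Overlaps of calls between comparisons were set against the number chance would give. Correlations and covariances across probe sets were set beside 50 simulations with no change in any group but shared control arrays. They were also computed over 20 divisions of the WT dark arrays. Changes within a comparison can move r away from its simulated value, so a simulated r is no baseline for the data. The steps were tested on simulated data with 200 of 22746 probe sets changed by 1.5 on the log2 scale. Of these, 100% were recovered in the dark genotype effect, 100% in the WT 1 h red response and 99% in the seed genotype effect. None was called in the wrong direction, and 0, 0 and 3 unchanged probe sets were called. The simulated noise was independent between probe sets and arrays, so structure shared by the real arrays was not tested. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

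Alternatives tried were median centring and quantile normalization of the arrays, array weights, an intensity trend, a fit of the compared groups alone, a filter dropping the lowest 33.3% of probe sets, 1 probe set per gene, no fold minimum, the replicate number as a block, dark replicates 1 to 3 or 4 to 6 alone, and each array left out in turn.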

Results

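Transcript levels were measured on 30 Affymetrix Arabidopsis arrays, each hybridized with RNA from whole seedlings (root, hypocotyl and cotyledon) or from stratified seed. The samples came from wild-type Col-0 (WT) and from a quadruple mutant, pifq, that lacks the phytochrome-interacting factors PIF1, PIF3, PIF4 and PIF5. These basic helix-loop-helix transcription factors accumulate in darkness, hold back seedling greening and are removed after red light activates the phytochrome photoreceptors. Each genotype was sampled in 4 conditions: seed stratified for 5 d at 4 °C (n = 3), seedlings grown for 2 d in darkness (n = 6), dark-grown seedlings given 1 h of red light at 7.5 µmol/m2/s (n = 3), and seedlings kept in continuous red light at 6.7 µmol/m2/s for 45 h (n = 3). Array medians lay between 4.91 and 5.22 on the log2 scale, and the number of arrays per group limits the precision of each value. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples. Of 22746 probe sets tested, 1038 differed between the genotypes in darkness and 39 in continuous red light. The transcripts of the 4 targeted PIF genes were not analysed here.

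**Figure D1:**
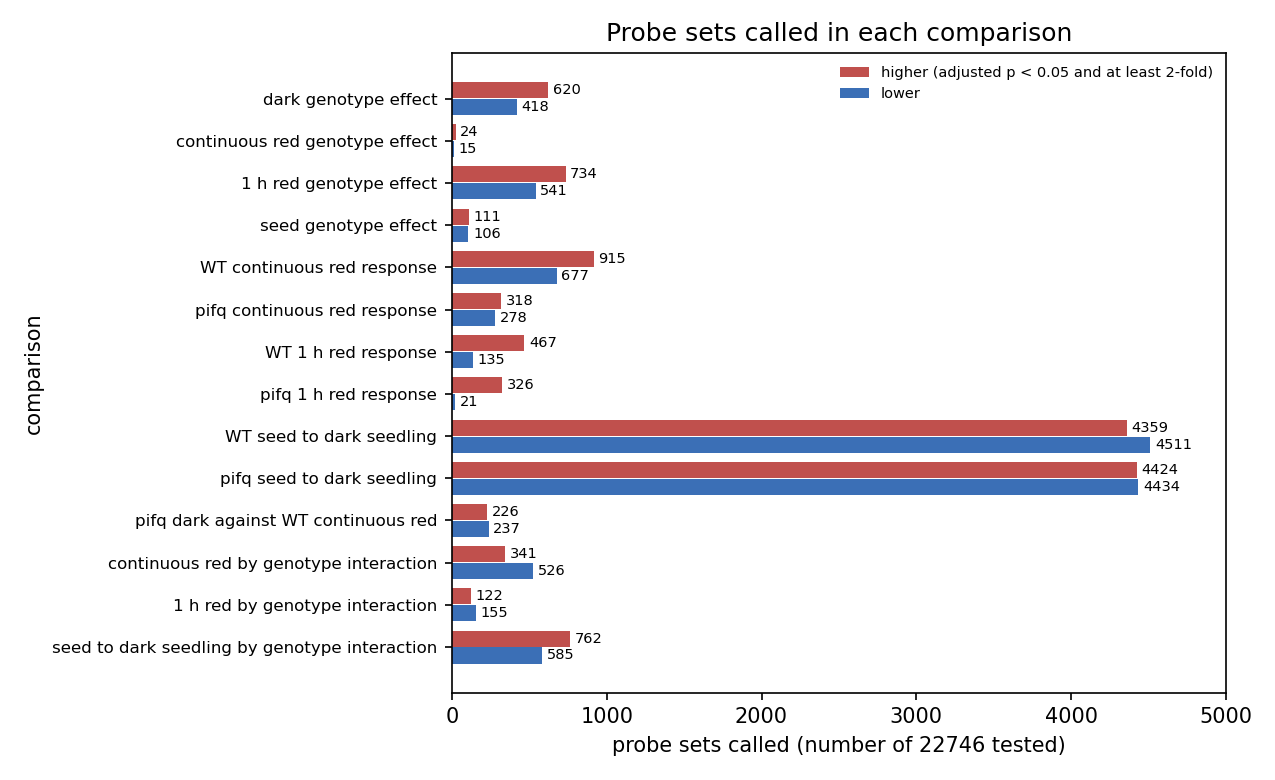
Number of probe sets called higher (red) or lower (blue) in each of the 14 comparisons, at an adjusted p under 0.05 and at least 2-fold. The genotypes differed at 1038 probe sets in darkness and at 39 in continuous red light.

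The comparison of dark-grown pifq with dark-grown WT asks which transcripts depend on the 4 PIFs in darkness. Some transcripts of the photosynthetic apparatus were more abundant in pifq. PSAN, a subunit of photosystem I, had a log2 level of 12.24 ± 0.10 in pifq and 9.83 ± 0.12 in WT (SD, n = 6 each), a 5.32-fold difference. LHCB4.2, a minor antenna protein of photosystem II, was 6.24-fold higher, and CaS, a calcium-sensing protein of the thylakoid, was 6.70-fold higher. Other genes went the other way: the late-embryogenesis gene M17 lay at 3.01 ± 0.15 in pifq and 8.37 ± 0.45 in WT (SD, n = 6 each), and the vicilin-like storage protein gene PAP85 was 25.2-fold lower. QQS, a species-specific gene tied to starch content, had the largest increase among the named genes, from 4.07 ± 0.41 in WT to 10.30 ± 0.29 in pifq (SD, n = 6 each).

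In total, 620 probe sets were higher and 418 lower in dark pifq (limma, adjusted p under 0.05 and at least 2-fold), and the remaining probe sets did not pass. Among the genes with a symbol, the increases with the largest log2 differences were QQS at 6.23 (SE 0.17, adjusted p = 2.87e-21), ECS1 at 4.01 (SE 0.10, adjusted p = 3.72e-22) and the methionine sulfoxide reductase gene MSRB6 at 3.95 (SE 0.17, adjusted p = 5.52e-17). They were followed by the cytokinin response regulator RR16 (3.15), CaS (2.74), LHCB4.2 (2.64), the vacuolar sugar transporter SWEET2 (2.50) and PSAN (2.41). Among the genes with a symbol, the decreases were led by M17 at -5.36 (SE 0.14, adjusted p = 1.42e-21), PAP85 at -4.66 (SE 0.17, adjusted p = 1.56e-18) and LEA18 at -3.95 (SE 0.19, adjusted p = 7.55e-16). The expansin gene EXPA9 (-3.53), the late-embryogenesis genes M10 (-3.32), LEA (-3.31) and AtLEA4-1 (-2.95) and the MADS-box gene AGL67 (-2.89) came next. M17 and AGL67 lay under the lower quartile of all probe sets in dark pifq (3.59), where background was not separated from expression, so their differences and ranks are at best bounds, as for M17 elsewhere. That no array of one genotype overlapped the other genotype's arrays for these 16 genes was a condition of the naming rule and not a result. Leaving out any 1 array changed no call among the genes named for this comparison.

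Of the lists of greening genes, 2 held with either correlation in dark pifq. They share genes, PSAN, PSAE-1 and PSBY among them, so they are not separate evidence, here or in later comparisons. All 4 measured photosystem and electron transport subunits were higher in dark pifq, 4 of 4 also when adjusted over the list alone, among them PSAE-1 (2.04), PSBY (1.62) and PSBW (1.45), and the list test held with either correlation (camera adjusted p = 3.18e-11; adjusted p = 3.15e-05 with an estimated correlation). Of 29 nuclear genes for thylakoid complexes and their assembly, 14 were higher and none lower, with a list median of 0.82 (camera adjusted p = 2.56e-26; adjusted p = 0.00116 with an estimated correlation); NdhL was among them (2.14). Of 3 light-harvesting genes 2 were higher, LHCB4.2 and LHCB4.1 (1.90), the same number adjusted over the list alone (camera adjusted p = 0.0512 with an estimated correlation). All 3 are LHCB4 genes, the only ones measured of the 20 on the list. Of 8 tetrapyrrole and chlorophyll synthesis genes 4 were higher, the same number adjusted over the list alone, including HEME1 (1.59) and the methyltransferase gene CHLM (1.38; adjusted p = 0.158 with an estimated correlation). In the Calvin cycle the Rubisco activase gene RCA was higher (1.59), the only 1 of 3 measured genes to pass, also when adjusted over the list alone (adjusted p = 0.0856 with an estimated correlation). The plastid genome's own photosynthesis genes showed a median of 0.86, with 10 of 45 higher, psbB among them (1.41; adjusted p = 0.101 with an estimated correlation), whereas none of 19 plastid genes for gene expression was called by limma at a median of 0.61, with 17 at an unadjusted p under 0.05 (adjusted p = 0.196 with an estimated correlation). None of 15 mitochondrially encoded genes was called by limma, with 3 at an unadjusted p under 0.05.

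Some genes tied to growth were lower in dark pifq, but no list of such genes held its call with an estimated correlation. The auxin-response repressor IAA29, known as a gene induced by shade, had a log2 level of 5.27 ± 0.23 against 7.59 ± 0.26 in WT (SD, n = 6 each; log2 difference -2.32). FHL, which carries phytochrome A into the nucleus, differed by -2.03. Of 8 cell wall loosening genes 3 were lower, the same number adjusted over the list alone: the xyloglucan endotransglucosylases XTH19 (-1.62), XTH33 (-1.36) and XTH18 (-1.34; adjusted p = 0.0515 with an estimated correlation). Over all 28 expansin and xyloglucan endotransglucosylase genes 7 were lower and none higher (adjusted p = 0.0983 with an estimated correlation). Of 15 cold and dehydration genes 5 were lower (adjusted p = 0.0770 with an estimated correlation). The auxin gene IAA34 was higher (1.29), though not called with dark replicates 4 to 6 alone (1.0). In other families the beta-glucosidase BGLU19 was lower (-1.99), and called members went both ways: the glutathione transferases GSTU18 (1.91) and GSTU22 (-1.28), and AGL87 (1.67) and AGL67.

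**Figure D2:**
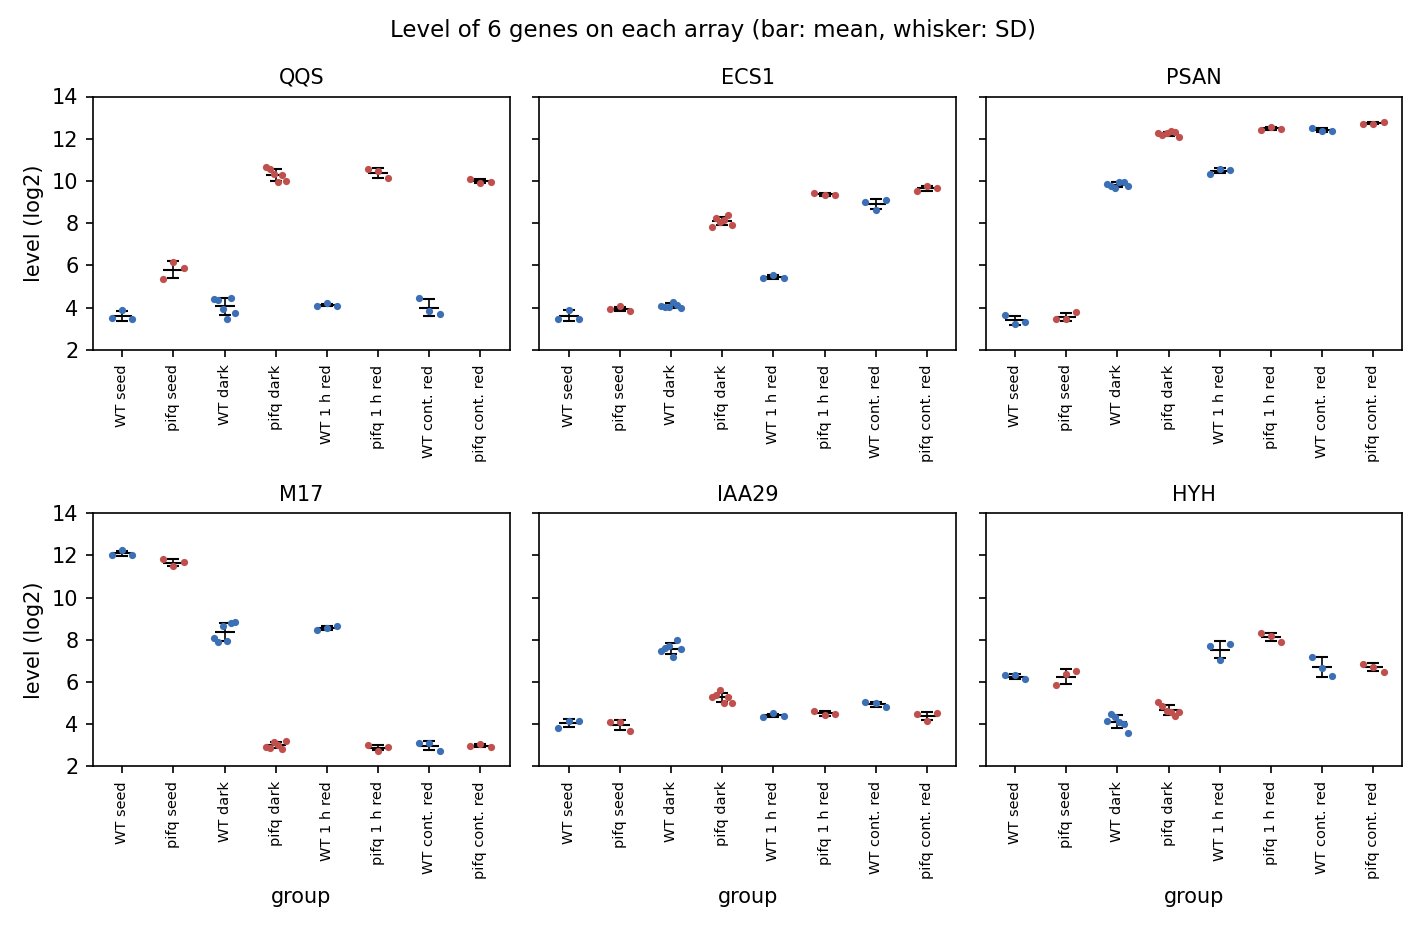
Log2 level of 6 genes on each array (points; blue WT, red pifq) with the mean (bar) and SD (whisker) of each group, n = 6 in darkness and n = 3 elsewhere. QQS stayed high in pifq seedlings in each light condition, while M17 in WT went from 8.37 ± 0.45 in darkness to 2.99 ± 0.22 in continuous red light.

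The response of WT to continuous red light gives the change that light itself brings to normal seedlings. ECS1 rose from 4.09 ± 0.11 (SD, n = 6) to 8.92 ± 0.24 (SD, n = 3), and PSAN from 9.83 ± 0.12 (SD, n = 6) to 12.41 ± 0.10 (SD, n = 3). CHIL, a chalcone isomerase-like gene, rose 9.69-fold and DFR, a dihydroflavonol reductase gene, 5.25-fold, at best a bound since it lay under the lower quartile in dark WT. M17 dropped to 2.99 ± 0.22 (SD, n = 3), and the oil-body protein gene OLEO3 was 10.6-fold lower. 1592 probe sets were called, 915 higher and 677 lower.

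Among the named increases were ECS1 at 4.83 (SE 0.12, adjusted p = 1.71e-21), MSRB6 at 4.29 (SE 0.21, adjusted p = 1.08e-15), the thionin gene THI2.2 at 3.3 (SE 0.17, adjusted p = 4.32e-15), CHIL (3.28), the dehydrin gene LTI30 (3.18), RR16 (3.02), SWEET2 (2.85) and LHCB4.2 (2.62). M17 at -5.38 (SE 0.17, adjusted p = 1.52e-19), PAP85 at -4.51 (SE 0.21, adjusted p = 4.18e-16), LEA18 (-4.48), the defensin-like gene LCR67 (-3.94), M10 (-3.46), OLEO3 (-3.41), LEA (-3.3) and the pectin methylesterase gene ATPMEPCRD (-3.13) fell. HYH, a bZIP partner of the light regulator HY5, rose by 2.59, FHL changed by -2.50 and IAA29 by -2.64. The stomatal lineage regulator SPCH rose by 1.47, the only 1 of 3 stomatal genes to pass, also when adjusted over the list alone (adjusted p = 0.0515 with an estimated correlation). All 4 photosystem subunits rose, as did 2 of 3 light-harvesting genes, the same numbers adjusted over the list alone. Of 29 thylakoid genes 16 rose. The photosystem, thylakoid and light-harvesting lists held with an estimated correlation (camera adjusted p = 3.15e-05, 8.58e-04 and 0.0269). The thylakoid list shares genes with each of the others, and the light-harvesting list holds LHCB4 genes alone. All 3 Calvin cycle genes rose, SBPASE by 1.14 and RCA by 1.89, the same number adjusted over the list alone (adjusted p = 0.0770 with an estimated correlation). Of 8 tetrapyrrole genes 4 rose, the same number adjusted over the list alone (adjusted p = 0.186 with an estimated correlation). Of 45 plastid photosynthesis genes 15 rose, including psaA (1.95; 1.48 higher in dark replicates 4 to 6 than in 1 to 3) and petL (1.35; adjusted p = 0.132 with an estimated correlation). XTH33 (-2.37), XTH19 (-2.3) and XTH18 (-2.05) fell, 3 of 8 cell wall loosening genes, the same number adjusted over the list alone (adjusted p = 0.0770 with an estimated correlation). Among 49 family 1 glycosyltransferases 4 rose, led by the flavonoid enzymes UGT78D2 (2.3) and UGT78D1 (1.85), and 1 fell.

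Loss of the 4 PIFs in darkness and red light in WT changed many of the same transcripts in the same direction. Of the 620 probe sets higher in dark pifq, 511 also rose in WT under continuous red light, against 24.9 from chance overlap. Of the 418 lower ones, 308 also fell, against 12.4 from chance, and 8 moved in opposite directions. Calls in the same direction made up 78.9% of the dark genotype calls and 51.4% of the WT red calls. QQS was an exception, with no call in the WT red response, whereas ECS1, MSRB6, PSAN, M17 and PAP85 were called in both. Both comparisons subtract the same WT dark arrays, which by itself correlates their differences. Across probe sets, which are not independent replicates, r was 0.812 and the covariance 0.237. Simulated arrays with no change in any group gave an r of 0.408 and a covariance of 0.00713. The simulated r is no baseline for data with large changes, so only the covariances can be set against each other. With the 6 WT dark arrays divided 3 and 3 between the comparisons in 20 ways, r ranged from 0.589 to 0.813 and the covariance from 0.195 to 0.237. Between 451 and 517 probe sets then rose in both, between 278 and 326 fell in both, and up to 38 moved in opposite directions.

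**Figure D3:**
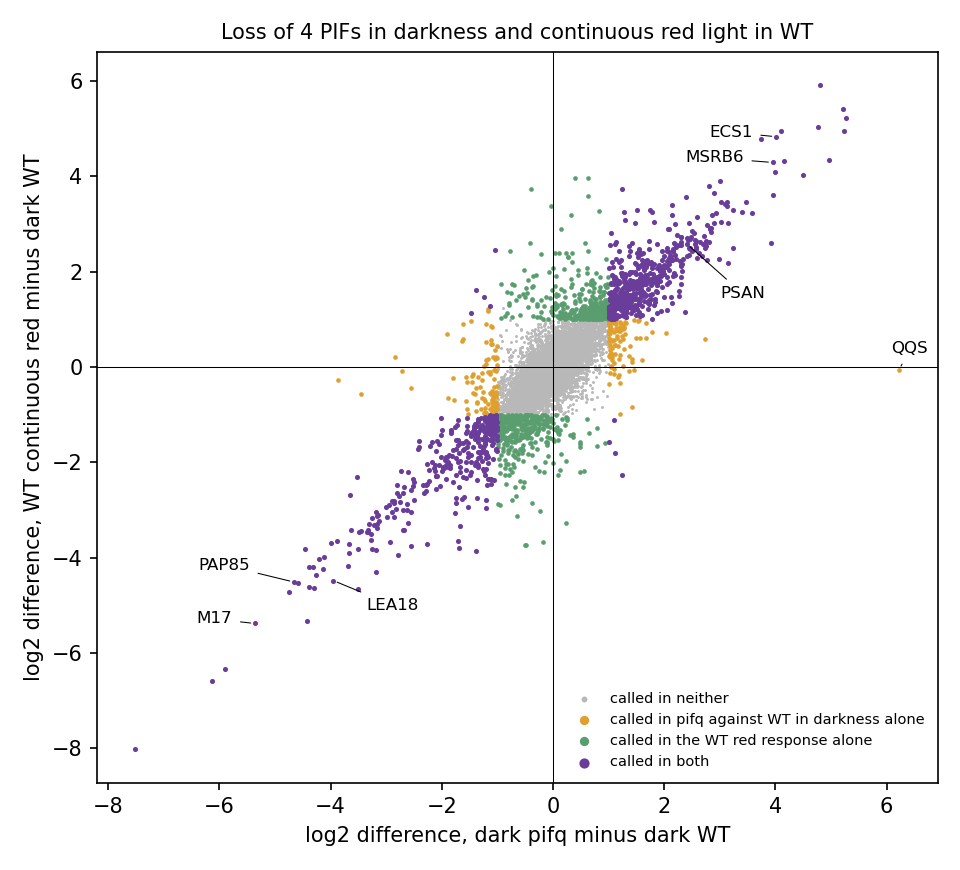
Log2 difference of each of 22746 probe sets between dark pifq and dark WT (horizontal axis) and between WT in continuous red light and dark WT (vertical axis). Probe sets called in both (purple) lie along the diagonal, with r at 0.812 across probe sets. Simulated arrays with shared WT arrays and no change in any group gave 0.408, which is no baseline for data with changes. QQS lies off the diagonal.

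In pifq, fewer probe sets were called in continuous red light than in WT. LTI30 rose from 6.50 ± 0.75 (SD, n = 6) to 9.56 ± 0.09 (SD, n = 3), although it differed by -1.09 between dark replicates 4 to 6 and 1 to 3. DFR and CHIL rose by 2.39 and 2.33. ATPMEPCRD fell by 2.25 on the log2 scale, P1R3 changed by -2.13 and the glutamine amidotransferase-like gene GAT1_2.1 by -1.67; a second probe set of GAT1_2.1, at a mean level of 3.28, differed by -0.13. The clock gene GI rose by 1.24, the root hair expansin gene EXPA7 by 1.59 and HYH by 2.00, while the auxin-regulated genes IAA20 (-1.54) and HAT2 (-1.52) fell. 596 probe sets were called, 318 higher and 278 lower (901 with the replicate number as a block, against 1842 in WT); 209 of the increases and 194 of the decreases were shared with WT, and 8 went in opposite directions. None of 4 photosystem subunits was called by limma, adjusted over the list alone as well, with 2 at an unadjusted p under 0.05 (adjusted p = 0.0512 with an estimated correlation), and 2 of 29 thylakoid genes did (adjusted p = 0.0374 with an estimated correlation). Of 22 auxin genes 3 fell (adjusted p = 0.0269 with an estimated correlation).

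The responses to continuous red light differed between the genotypes when the difference itself was tested. The interaction was called at 867 probe sets, 341 with a higher and 526 with a lower response in pifq than in WT. A smaller fall counts as a higher response. M17 (5.36), PAP85 (4.44) and LEA18 (4.1) fell in WT, and M17 lay at 3.01 ± 0.15 in dark pifq (SD, n = 6) and 2.99 ± 0.07 in pifq in continuous red light (SD, n = 3), under the lower quartile of each group, where a further fall could not be seen. RR16 (-3.80), MSRB6 (-3.54) and ECS1 (-3.28) had a lower response in pifq than in WT. All 4 photosystem subunits and 12 of 29 thylakoid genes had a smaller response in pifq (adjusted p = 2.57e-05 and 0.00469 with an estimated correlation), the first count being the same adjusted over the list alone. Of 100 random genotype labellings, 2 including the real one called as many probe sets.

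In continuous red light few probe sets differed between the genotypes. 39 were called, 24 higher and 15 lower in pifq, and with each array centred on its median the numbers were 29 higher and 11 lower. QQS remained higher, at 9.99 ± 0.09 in pifq and 4.01 ± 0.40 in WT (SD, n = 3 each), a log2 difference of 5.99 (SE 0.24, adjusted p = 5.73e-16). GH3.3, which conjugates auxin to amino acids, was lower in pifq by a log2 difference of -1.15 (SE 0.21, adjusted p = 0.00376). It was the only 1 of 4 auxin response genes to pass, also when adjusted over the list alone (adjusted p = 0.0512 with an estimated correlation). No thylakoid gene was called by limma, with 7 of 29 at an unadjusted p under 0.05, and their median was 0.23 (adjusted p = 0.0770 with an estimated correlation). Over all genes 2623 probe sets had an unadjusted p under 0.05. Dark pifq and WT in continuous red light were also compared directly, and 463 probe sets differed, 226 higher and 237 lower in dark pifq. QQS (6.29), ATPMEPCRD (2.49) and FDH (1.94) were higher in dark pifq, and LTI30 (-2.86), CHIL (-2.46), DFR (-2.36), the AP2-domain gene tny (-2.42) and HYH (-2.01) were lower. None of the photosystem, light-harvesting, Calvin cycle or tetrapyrrole genes was called by limma in this comparison, adjusted over the list alone as well, with 0 of 4, 1 of 3, 0 of 3 and 1 of 8 at an unadjusted p under 0.05.

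The 1 h red light groups address which transcripts respond first. HYH rose in WT from 4.11 ± 0.31 (SD, n = 6) to 7.52 ± 0.41 (SD, n = 3), and the clock gene GI rose 7.89-fold. SMZ and SNZ, which encode AP2-type repressors of flowering, rose 12.8-fold and 7.22-fold. IAA29 fell to 4.41 ± 0.09 (SD, n = 3), and EXO, a gene promoted by brassinosteroids, was 5.59-fold lower. PSAN lay at 10.48 ± 0.12 (SD, n = 3) and did not pass the 2-fold minimum.

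602 probe sets were called in WT after 1 h, 467 higher and 135 lower. THI2.2 at 4.14 (SE 0.17, adjusted p = 4.26e-17), MSRB6 at 3.87 (SE 0.21, adjusted p = 1.68e-14), SMZ at 3.67 (SE 0.16, adjusted p = 1.49e-16), UGT78D2 (3.67), HYH (3.41), the F-box gene AFR of far-red signalling (3.12), GI (2.98) and SNZ (2.85) rose most among the named genes. IAA29 at -3.17 (SE 0.14, adjusted p = 2.26e-16), EXO at -2.48 (SE 0.20, adjusted p = 1.89e-10), FHL (-1.70), IAA20 (-1.32), the kinase gene WAG2 of auxin transport (-1.31), the organ-size gene ARL (-1.30), GAT1_2.1 (-1.20) and WRKY22 (-1.14) fell. GAT1_2.1, whose second probe set differed by -0.17, was no longer called with dark replicates 4 to 6 alone (-0.74), nor WRKY22 with dark replicates 1 to 3 alone or a replicate block (-0.97 each). Of 4 auxin response genes 1 fell, IAA29, the same number adjusted over the list alone, at a list median of -0.45 (camera adjusted p = 0.0147 with an estimated correlation). The others were not called: GH3.3 differed by -0.88, and YUC2 and WES1 by -0.01 each. Of 3 light-harvesting genes 2 rose, the same number adjusted over the list alone, with LHCB4.3 at 1.31 (adjusted p = 0.0512 with an estimated correlation). LHCB4.2, the other, was under the 2-fold minimum without WT dark replicate 1 (0.96) or 2 (0.99), without WT 1 h red replicate 1 (0.98), or with dark replicates 4 to 6 alone (0.76). The photosystem list shifted by a median of 0.31 with none of 4 genes called by limma, adjusted over the list alone as well, and 4 at an unadjusted p under 0.05 (adjusted p = 0.0221 with an estimated correlation). No tetrapyrrole or Calvin cycle gene was called by limma, adjusted over the list alone as well, with 0 of 8 and 0 of 3 at an unadjusted p under 0.05. Nor was any plastid-encoded photosynthesis gene, with 4 of 45 at an unadjusted p under 0.05. Members of other families were called too, such as GSTU16 (1.35), UGT78D1 (1.93), XTH32 (1.45), LEA4-5 (1.28) and LTI30 (1.83), with XTH33 lower (-1.11; -0.98 with dark replicates 4 to 6 alone).

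The early and the lasting red response of WT shared 208 increases and 87 decreases, against 18.8 and 4.02 from chance overlap, and 13 probe sets moved in opposite directions. THI2.2, MSRB6 and HYH rose in both. Across probe sets r was 0.372 and the covariance 0.0878. Simulated arrays with no change in any group gave 0.333 and 0.00714. With divided dark arrays r averaged 0.323, between 198 and 220 probe sets rose in both, between 67 and 99 fell in both and up to 52 moved in opposite directions. The early WT response also overlapped the dark genotype effect. There 128 probe sets were higher in both and 57 lower in both, against 12.7 and 2.48 from chance. In opposite directions 19 moved (up to 28 with divided arrays). For this pair r was 0.290 and the covariance 0.0577, and r averaged 0.235 with divided arrays. Simulated arrays with no change in any group gave 0.410 and 0.00718. As those groups held no changes, an r under the simulated one does not mean less likeness than shared arrays give.

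In pifq more probe sets rose than fell after 1 h. HYH rose by 3.44 (SE 0.20, adjusted p = 2.48e-13), THI2.2 by 2.86 (SE 0.17, adjusted p = 5.49e-13), LTI30 by 2.36, LEA4-5 by 2.25, GSTU16 by 1.57 and GI by 1.56. WAG2 fell by 1.39 on the log2 scale and ARL by 1.07. ARL dropped under the 2-fold minimum without pifq dark replicate 5 (-1.0) or pifq 1 h red replicate 3 (-0.93), with dark replicates 1 to 3 alone (-0.92), or with a replicate block (-0.93). 326 probe sets rose and 21 fell (415 and 111 with dark replicates 4 to 6 alone), and 219 increases and 16 decreases were shared with WT, with 1 opposite. The interaction was called at 277 probe sets, 122 with a higher and 155 with a lower response in pifq, a smaller fall counting as higher. IAA29 (2.41) and EXO (2.31) fell in WT, and their positive differences mean a smaller fall in pifq. The sucrose-phosphate synthase gene ATSPS4F (1.59) rose more in pifq than in WT. MSRB6 (-3.05), tny (-1.96) and the wax ester synthase gene WSD1 (-1.73) had a lower response in pifq. IAA29 lay at 5.27 ± 0.23 in dark pifq (SD, n = 6) and reached 4.51 ± 0.10 after 1 h (SD, n = 3). Of 100 random genotype labellings, 8 including the real one called at least 277 probe sets in this interaction.

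After 1 h of red light 72.2% of the genotype calls made in darkness were called again in the same direction. Of the calls after 1 h, 58.7% had been made in darkness in the same direction. 1275 probe sets were called, 734 higher and 541 lower in pifq, of which 451 and 298 were also higher or lower in darkness and 3 were opposite. QQS (6.27), ECS1 (3.92) and CaS (2.3) were higher, and M17 (-5.66), PAP85 (-4.81) and M10 (-3.99) lower. All 4 photosystem subunits were higher, the same number adjusted over the list alone (adjusted p = 3.15e-05 with an estimated correlation), as were 17 of 29 thylakoid genes (adjusted p = 0.00206 with an estimated correlation) and 18 of 45 plastid photosynthesis genes (adjusted p = 0.107 with an estimated correlation). GI was lower in pifq (-2.00) and EXO higher (1.3), while IAA29 (0.10) and FHL (-0.49), lower in darkness, were not called.

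**Figure D4:**
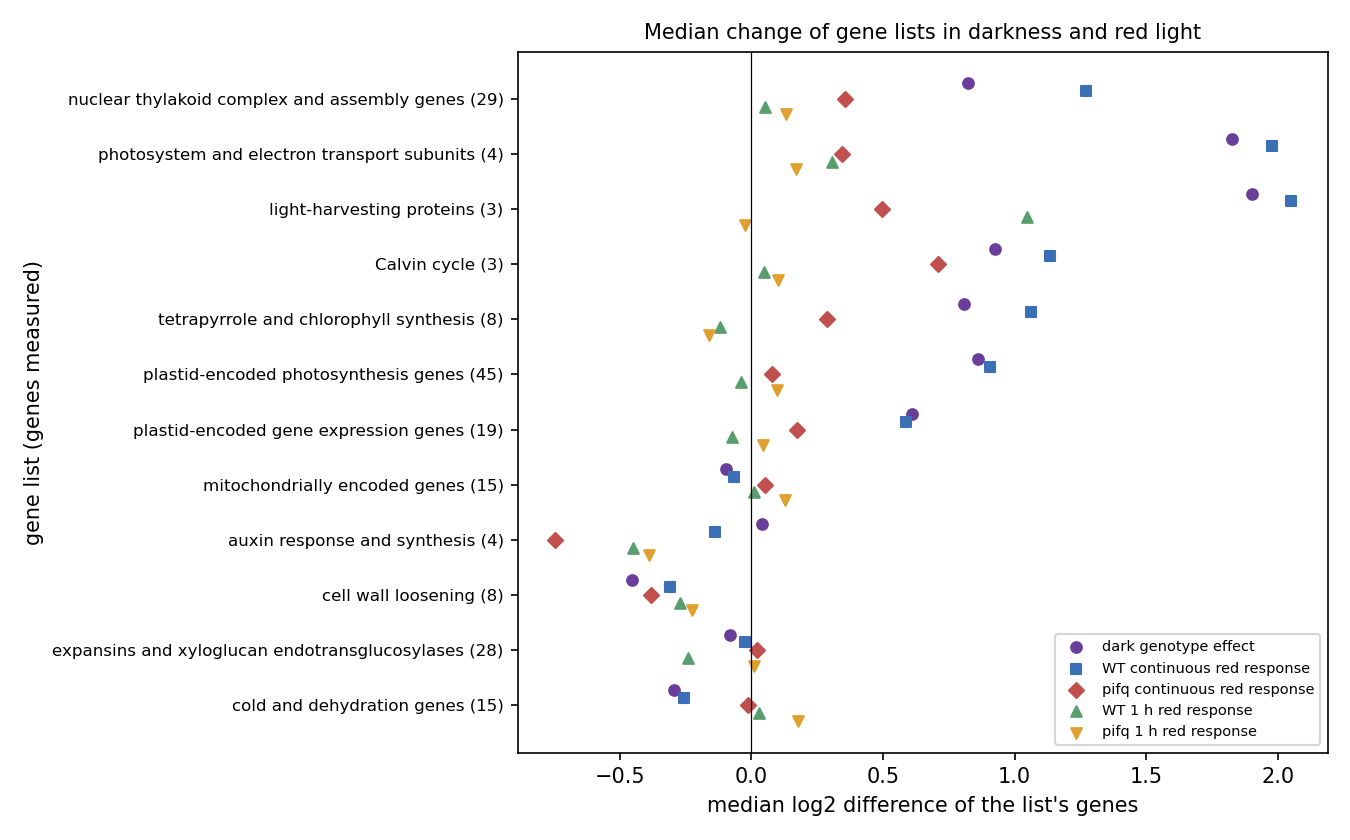
Median log2 difference of the measured genes of 12 gene lists (number of genes in parentheses) in the dark genotype effect and in the red responses of each genotype. The photosystem list had a median of 1.83 in the dark genotype effect and 1.98 in the WT continuous red response, against 0.34 in the pifq continuous red response.

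Seeds of the genotypes differed at fewer probe sets than dark seedlings did. FHL had a log2 level of 3.81 ± 0.13 in pifq and 6.25 ± 0.30 in WT (SD, n = 3 each), and XERICO, a RING-type gene tied to abscisic acid content, was 4.47-fold lower in pifq. GID1A, a gibberellin receptor gene, was lower (-1.15), the only 1 of 3 measured gibberellin genes to pass, also when adjusted over the list alone (adjusted p = 0.0144 with an estimated correlation). The expansin genes EXPA8 (2.1) and EXPA9 (1.27) and XTH19 (1.38) were higher. 217 probe sets were called, 111 higher and 106 lower in pifq, and 7 and 20 of them were called in the same direction in darkness, against 3.03 and 1.95 from chance overlap, with 10 opposite. The named genes were the carboxypeptidase-like scpl44 at 2.28 (SE 0.12, adjusted p = 1.55e-13), QQS at 2.19 (SE 0.24, adjusted p = 2.54e-07) and the asparaginase gene ASPGB1 (2.16), and, lower, FHL at -2.44 (SE 0.20, adjusted p = 1.52e-09), IAA30 (-2.32) and XERICO (-2.16). The cell wall loosening list, with 2 of 8 genes higher and the same number adjusted over the list alone, held with an estimated correlation (adjusted p = 0.0118 with an estimated correlation). The mitochondrially encoded genes had a median of -0.30, with cox1 lower (-1.26; adjusted p = 0.0336 with an estimated correlation).

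From stratified seed to dark seedling more probe sets changed than in any other comparison made. In WT 4359 probe sets rose and 4511 fell, and in pifq 4424 rose and 4434 fell, with 3759 increases and 3970 decreases shared and 6 opposite. Centring each array on its median would shift these differences by -0.254 in WT and -0.237 in pifq, since seed arrays had lower medians (4.91 to 4.94) than seedling arrays, and changes are given as deposited. PYK10, a beta-glucosidase of endoplasmic reticulum bodies, rose by 9.31 in WT and 8.77 in pifq, and the jacalin-related lectin gene JAL34 by 7.93 and 7.66. In WT MSRB9 rose by 8.16, and UGT76E12 (-7.53), LTI30 (-7.46) and the defensin gene PDF2.1 (-6.75) fell. In pifq PSAN rose by 8.67, and M10 (-9.28), PAP85 (-9.16) and M17 (-8.65) fell. PORB, a protochlorophyllide reductase gene, rose by 7.29 in WT and 6.89 in pifq. Of 45 plastid photosynthesis genes 41 rose in WT and 45 in pifq (adjusted p = 0.146 and 0.0994 with an estimated correlation). Of 15 mitochondrially encoded genes 7 fell in each genotype (adjusted p = 0.127 and 0.186 with an estimated correlation), cox1 by 3.28 on the log2 scale in WT. Among the cell wall loosening genes 7 of 8 rose in WT (adjusted p = 0.00892 with an estimated correlation) and 5 in pifq (adjusted p = 0.0989 with an estimated correlation), the same numbers adjusted over the list alone, with XTH18 at 6.22 and 4.46. Of 22 trichome birefringence-like genes 8 rose in WT and 9 in pifq (adjusted p = 0.00569 and 0.0118 with an estimated correlation).

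The change from seed to dark seedling differed between the genotypes at 1347 probe sets, 762 with a higher and 585 with a lower change in pifq. MSRB6 (4.21), QQS (4.05) and ECS1 (3.67) had higher changes in pifq, and M17 (-4.93), EXPA9 (-4.81) and PAP85 (-4.63) had lower changes there. M17 went from 12.09 ± 0.13 in WT seed and 11.66 ± 0.17 in pifq seed (SD, n = 3 each) to 8.37 ± 0.45 and 3.01 ± 0.15 in dark seedlings (SD, n = 6 each). All 4 photosystem subunits and 13 of 29 thylakoid genes had a larger increase in pifq (adjusted p = 3.15e-05 and 0.00316 with an estimated correlation), and 4 of 8 cell wall loosening genes a lower change (adjusted p = 0.00569 with an estimated correlation). The photosystem and cell wall counts were the same adjusted over the list alone.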

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

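Several tests here were chosen only after the result was seen. They were, for QQS, all but the other scalings, and for the dark arrays, all but quantile normalization. For the upward pifq response they were all of the tests. The relabelling with the shared genotype difference removed was also chosen then.

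Responses that differ between the genotypes came from the interaction tests. In the continuous red by genotype interaction, 867 probe sets were called, and 2 of 100 random labellings, the real one included, called as many (highest other 924). Among the genes with a symbol, the largest log2 differences of the responses were M17 at 5.36, PAP85 at 4.44, LEA18 at 4.1, RR16 at -3.80, MSRB6 at -3.54 and ECS1 at -3.28. The M17 value is at best a bound, since M17 lay at 3.01 in dark pifq, under the lower quartile there (3.59). For the change from seed to dark seedling, 1347 were called against a highest other of 334 in 100 labellings, with 1 as large, the real one. There MSRB6 differed by 4.21, QQS by 4.05, ECS1 by 3.67, M17 by -4.93, EXPA9 by -4.81 and PAP85 by -4.63.

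For the 1 h red by genotype interaction the count was 277, and 8 of 100 random labellings called as many (highest other 1788), so this test did not exclude chance. A labelling that calls several times the real count points to a structure of the samples: mixing genotypes within 1 condition turns the genotype difference into a difference of responses. With the shared genotype difference subtracted first, 1 of 100 labellings called as many, the real one, with a highest other of 239; the same test gave a highest other of 566 for continuous red and 1091 for seed to dark seedling, with 1 of 100 in each. IAA29 differed by 2.41, EXO by 2.31, ATSPS4F by 1.59, MSRB6 by -3.05, tny by -1.96 and WSD1 by -1.73.

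Single dark arrays lay apart from the other 5 of their group for 10 of 168 gene and group sets of 6 arrays, where about 8.4 would be so by chance. The gap to the nearest array was 0.776 of the whole range for ATSPS4F in pifq replicate 6, 0.741 for LHCB4.2 in pifq replicate 1 and 0.661 for LHCB4.3 in pifq replicate 4. In WT it was 0.778 for AtLEA4-1, 0.687 for LCR67 and 0.759 for PSAE-1 in replicate 4, 0.657 for EXPA9, 0.757 for petL and 0.626 for SNZ in replicate 1, and 0.738 for psbB in replicate 5. No pattern over the arrays was tested.

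QQS was the only named gene called higher in pifq in all 4 conditions. A single scaling factor per array left in the deposited values is argued against as its source. It would move every probe set alike, and at most 3.25% were at least 1 log2 unit higher in pifq in any condition. RMA had already equalized the array distributions, so this share tests little. Under the other scalings the lowest log2 difference was 2.17, but these moved the values by a median of at most 0.0404 and test little. An effect of PIF loss that red light also brings about in WT is argued against too, because QQS changed by -0.0610 in WT under continuous red light (SE 0.204) while it was 6.23 higher in dark pifq. A difference between the seed lines at this locus, independent of the 4 PIF genes, cannot be told apart from an effect of the mutations. The smallest difference, 2.19 in seed, is compatible with either, and the labels name 1 line for each genotype.

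The dark arrays numbered 1 to 3 lay apart from those numbered 4 to 6 in both genotypes. With genotype accounted for, 6053 of 22746 probe sets differed between the parts at an adjusted p under 0.05 (limma) with no fold minimum. With the 2-fold minimum 83 were called, 42 higher and 41 lower in 4 to 6. The highest other was 4 in 100 splits, so chance is unlikely. A single scaling factor per array left in the deposited values after RMA is argued against, since 49.4% of these went in the less frequent direction. After quantile normalization 92 were called, but it moved the values by a median of 0.0198, too little to test other scaling. The WT and the pifq difference between the parts correlated at 0.771 across probe sets (highest other 0.692 in 100 pairs of splits). That correlation restates that the parts lay apart in both genotypes, so it is no separate support for a cause. Handling or growth in sets shared by the genotypes remains a candidate explanation. Unequal exposure to red light cannot be told apart from this: the pifq parts correlated at -0.0887 with the WT 1 h red response and the WT parts at -0.353 with that of pifq, but with the continuous red responses the correlations were 0.122 and 0.38, of the same sign in both. HRGP1 (1.53), psaA (1.48), P1R1 (-1.34) and LTI30 (-1.09) were among the genes that differed, singled out after their values were seen.

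Of the calls in the 1 h red response of pifq, 93.9% were upward, against 77.6% in WT. A single upward scaling factor per array left in the deposited values is argued against. It would raise every probe set alike, and the median difference over all probe sets was -0.0271. RMA had already equalized the array distributions, so this value tests little. Other array scaling stays open: the share was 94.2% after quantile normalization, which moved the values by a median of 0.00961, too little to test it. A signal floor is argued against: of the 135 probe sets that fell in WT, 3.70% lay under the lower quartile of dark pifq levels. Levels already low in pifq before the light remain a candidate explanation, because over 20 divisions of the WT dark arrays the median pifq to WT difference of such probe sets in darkness was at most -0.514, and 57 of the 135 were called lower in dark pifq. The contrast depended on the dark arrays used: with dark replicates 4 to 6 alone, 526 were called in pifq, 415 higher and 111 lower, so 78.9% were upward, against 73.4% in WT.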

How the results depend on the processing

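All alternatives were planned except a block for dark replicates 1 to 3 and 4 to 6, which was chosen after seeing the data. It gave 1038 calls in the dark genotype effect, the number reported. Each part held as many WT as pifq dark arrays, so this block could not move the dark log2 differences, and its count tests little. No named gene reversed under any alternative tried. The list tests were rerun only with an estimated correlation and with median centring, and none reversed. An estimated correlation cannot move a list median. For named genes 6664 values kept their direction and side of the threshold, 74 became weaker and 88 passed only under the alternative; with 1 array left out these numbers were 6448, 116 and 24. For the list tests under their alternatives they were 459, 99 and 2, by whether the camera test passed.

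With no fold minimum more probe sets passed by construction: 6312 in the dark genotype effect, 204 in the continuous red, 4809 in the 1 h red and 1050 in the seed genotype effect. The WT responses counted 6402 (continuous red), 2095 (1 h red) and 15627 (seed to dark seedling), and those of pifq 3715, 1447 and 15768. Dark pifq against WT in continuous red gave 2511, and the interactions 2364 (continuous red), 542 (1 h red) and 3691 (seed to dark seedling).

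With 1 probe set per gene fewer were tested and fewer called: 503 in the dark, 12 in the continuous red, 648 in the 1 h red and 103 in the seed genotype effect. The WT responses counted 770, 221 and 4760, and those of pifq 285, 135 and 4747. Dark pifq against WT in continuous red gave 204, and the interactions 420, 94 and 647.

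In the continuous red genotype effect, the fit of the compared arrays alone called 23, with fewer arrays to estimate the spread. The pifq continuous red response rose to 901 with the replicate number as a block, and the pifq 1 h red response to 526 with dark replicates 4 to 6 alone; the cause was not tested. Of the list tests, 31 passed with an estimated correlation, which is larger than the preset one for most lists that lost their call, and 124 with median centring.

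The other settings left every count within 1.5 times the reported one. With 1 array left out the dark genotype effect ranged from 998 to 1089 and the continuous red genotype effect from 31 to 54. The replicate numbers were not used to pair the samples: 2 of the 6 WT dark arrays were closest to the pifq dark array of the same number, although the residuals of the 6 pairs with the same number correlated at 0.0117 to 0.637, 5 of them over 0.1. The pair under 0.1 holds the WT dark array that is replicate 3 in its title, used here, and replicate 2 in its description, so this tally and the replicate block rest on that title. A pseudocount could not be varied because the values are log2 already. The array weights stopped before their convergence tolerance. Signals near background were not separated from low expression. Named values that use a group under its lower quartile of all probe sets are at best bounds: M17, AGL67, WRKY22, IAA30, UGT76E12, ATSPS4F, WSD1, DFR in dark WT, PSAN in pifq seed, and QQS and ECS1 in WT seed.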

Other observations

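The test on seed transcripts was chosen only after the result was seen; the counts of splits were planned.

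Other splits of the same arrays were counted for each comparison of groups. For the dark genotype effect, 1 of 100 splits, the real one, called 1038 probe sets, with a highest other of 487, so chance is unlikely. The comparisons with 84 splits each had 1 as large, the real one, so chance is also unlikely there. The real count and the highest other were 1592 and 633 in the WT continuous red response and 596 and 259 in that of pifq. They were 602 and 223 in the WT 1 h red response and 347 and 161 in that of pifq. For the change from seed to dark seedling they were 8870 and 3459 in WT and 8858 and 3354 in pifq. Dark pifq against WT in continuous red light gave 463 and 199. The dark arrays lay apart by replicate number, so the arrays of a group were not freely exchangeable. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real count and the highest other were 39 and 0 in the continuous red genotype effect, 1275 and 0 in the 1 h red genotype effect, and 217 and 1 in the seed genotype effect, with 1 of 10 as large in each.

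The genotype effect was called in all 4 conditions for 1 probe set that was higher in pifq, QQS, and for 3 that were lower. In the 3 seedling conditions 9 were higher and 8 lower.

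M17 and PAP85, lower in dark pifq, are seed genes, so a candidate explanation was that most of the 418 lower probe sets are seed transcripts that dark WT seedlings still hold. Of the 418, 30.6% were more than 1 log2 unit higher in WT seed than in WT seedlings after 1 h of red light and 52.6% more than 1 lower. The shares were 20.5% and 19.4% of all probe sets, and 6.77% and 65.2% of the 620 higher in dark pifq. The median of seed minus seedling over the 418 was -1.33 (highest -1.24 with 1 array left out, 95% of resamples of the probe sets between -1.68 and -0.799). The resamples treat probe sets as independent, so they give no spread between samples. A transcript left over from seed should not be higher in seedlings than in seed, so the median argues against this as an account of most of the lower probe sets; for those higher in seed it stays open.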
